A study of Mus musculus with 12 samples.

How the data were processed

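RNA-seq was analysed for 12 libraries of mouse hematopoietic stem cells (HSCs) that had received a retrovirus and were sorted for green fluorescence. Per the labels' protocols, RNA from 5000 sorted cells per sample was converted to cDNA with the SMART-Seq HT kit. Libraries were then made with the Nextera XT kit and sequenced as 150 bp read pairs on a NovaSeq6000, per the same protocols. This chemistry carries no molecular identifiers, so the limits that a count of 0 allows cover counting error alone. It also does not mark strand, and neither the strand setting nor the annotation of the counting is given in the sources used here. Reads of a gene and of an overlapping or antisense neighbour are therefore not separable.

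Per the submitters' processing notes, the authors aligned the reads to mm10 with STAR 2.7.10, counted them per gene with featureCounts and used DESeq2 1.30.1 under R 4.3.0. The deposited count table held raw counts per gene for 35976 gene symbols in each of the 12 libraries. The authors also deposited a normalized signal for 15862 of these genes. Each of its columns was checked to be the count column divided by 1 constant, with a highest relative deviation of 5.1e-15. All values of both tables were assigned to a library, and 0 columns were left unused.

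The libraries formed 4 groups of 3, young_mock, young_Pbx1, old_mock and old_Pbx1. All tests were computed from the deposited counts with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the group as its argument and a minimum count of 10, which left 15335 genes. Library sizes were scaled by TMM. A single quasi-likelihood model with 1 mean per group and 8 residual degrees of freedom served all comparisons. The contrasts were young_Pbx1 over young_mock, old_Pbx1 over old_mock, old_mock over young_mock, old_Pbx1 over young_Pbx1, and the difference between the first pair of contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose" and "fell" are used for called genes. Levels are CPM, counts scaled to a common library size with the TMM factors, given as the mean ± SD of 3 libraries. Fold changes are on the log2 scale and followed by ± SE.

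Gene lists numbered 32 and were fixed, with the design, the tests and the alternatives, before the data were examined. They covered stem cell, aging, lineage, cell cycle, stress, immune and metabolic programs and sex-linked genes. Of 832 distinct symbols in the lists, 816 matched the count table as written, 15 by another name and 1 not at all. Lists were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01 among members. The test was repeated with a correlation estimated from the data and with fry. Counts "adjusted over the list alone" use the adjusted p over the members of 1 list. The genes named in the text follow a fixed rule. It takes Pbx1, Pbx2, Pbx3, Pbx4, Meis1 and Hoxa9. It adds the 10 risen and 10 fallen genes of each comparison with the largest fold change. These needed a mean of at least 10 CPM in the higher group and ranges that did not overlap, and predicted genes were left out. It also adds up to 4 members per list with the smallest adjusted p. Genes named outside this rule are marked as chosen after their values were seen. A fold against a group with 0 counts is given as a bound against a floor of 3 counts over the group.

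Positions are those of the RefSeq annotation of GRCm38, the assembly that mm10 names, and 14259 of the 15335 tested symbols matched it. The deposited symbols of near-identical gene copies, such as Hspa1a and Hspa1b, Akr1c12 and Akr1c13, and the H2 genes, can share reads, so their separate values are uncertain.

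Depth ranged from 38657236 to 59667802 counts per library. The model was tested on simulated data with the real means, depths and spreads, with 50 of the 15335 genes changed at each of 4 fold sizes. The changed genes were drawn without those of low mean level, so the shares recovered do not cover genes with low counts. For the young Pbx1 comparison it recovered 28% of the genes changed 1.5-fold, 56% at 2-fold, 84% at 4-fold and 100% at 8-fold. For the old Pbx1 comparison these shares were 36%, 58%, 86% and 92%, and for age in mock libraries 32%, 80%, 90% and 90%. False calls made up 2.9%, 2.16% and 3.31% of the calls in these simulations.

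The effect of age in mock libraries and the effect of Pbx1 share a mock group, so their covariance across genes was set beside that of 20 simulations with unchanged groups. Alternatives recomputed the gene counts with DESeq2's size factors in edgeR and with the replicate number as a block. They took no filter on low counts, or a strict filter of 10 CPM in 3 libraries. They also took library sizes without Pbx1, DESeq2 1.42.0's Wald test, limma-voom and limma on the normalized signal. Further fits used the compared groups alone, other than for the interaction, or left out each library in turn. The lists, the shared genes and the covariance were recomputed under part of these alternatives. Added after the data were seen were the replicate number as a block within each age, age effects without genes on X and Y, and a covariance with no shared old_mock library. The ATAC-seq that the labels mention was not analysed here.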

Results

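The data were RNA-seq counts of mouse HSCs, the bone marrow cells that renew all blood lineages. The young cells came from mice aged 2.5 months, with 4 mice pooled per sample, and the old cells from mice aged 18 months, with 1 mouse per sample. The cells had been sorted as CD150+, CD48- and CD34- within the LSK population of immature marrow cells. A further gate against CD41, a platelet-lineage protein, was set for the young cells alone. Each preparation was infected with an empty retrovirus carrying a green fluorescent reporter, called mock, or with 1 that also carried Pbx1, a homeobox transcription factor. Green cells were taken on day 3. There were 3 libraries in each of 4 groups. The young_mock libraries held 59667802, 51630201 and 49159840 counts, and the young_Pbx1 libraries 45647436, 42741260 and 39993595. The old_mock libraries held 54814542, 40681264 and 47855902 counts, and the old_Pbx1 libraries 44312143, 38657236 and 46461298. The 10 most abundant genes took between 5.09% and 7.10% of the counts of a library. On the first principal component, with 33.3% of the variance, the libraries split by age. The library old_Pbx1 replicate 2 lay apart on the component with 8.33% of the variance, at 58.71.

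The Pbx1 gene, on chromosome 1 from 168119364 to 168432365, was not higher in the libraries labelled Pbx1. In the young_mock libraries it stood at 26.83, 22.14 and 18.24 CPM, and in the young_Pbx1 libraries at 13.14, 13.28 and 15.87 CPM. The log2 fold change was -0.67 ± 0.16 (adjusted p = 0.108, edgeR), with a 95% interval from -1.05 to -0.289. Without young_mock replicate 3 the fall was called, at -0.80 with an adjusted p of 0.0425. Pbx1 also fell by DESeq2's test, where its adjusted p was 0.00887. In the old libraries Pbx1 stood at 37.45, 45.89 and 33.0 CPM with mock and at 33.52, 37.31 and 34.75 CPM with the Pbx1 label. Here the log2 fold change was -0.14 ± 0.16 (adjusted p = 0.775), with an interval from -0.514 to 0.234. The count table held 0 entries named for a vector, a reporter or a transgene. All directions below are therefore given between libraries labelled Pbx1 and mock, not between measured Pbx1 levels.

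**Figure D1:**
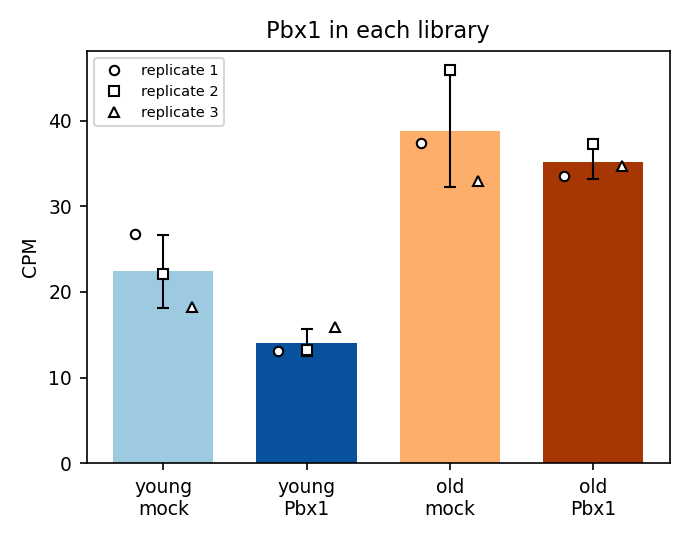
Pbx1 in each library, in CPM on the y axis, for the 4 groups on the x axis. Bars are means (22.4, 14.1, 38.8 and 35.2 CPM for young_mock, young_Pbx1, old_mock and old_Pbx1), error bars are SDs of 3 libraries, symbols are single libraries, and neither Pbx1-labelled group lies above its mock group.

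The first question was what the Pbx1 vector changed in young HSCs. The libraries labelled Pbx1 held more transcripts of the stem cell genes Hlf and Procr, and fewer of the granule enzyme genes Mpo and Gzmb and of Cd48, than the mock libraries. Hlf, which encodes a transcription factor of HSCs, rose from 34.6 ± 0.809 to 92.7 ± 9.51 CPM (SD, n = 3 each). Procr, the gene of a surface receptor used to isolate HSCs, rose from 9.02 ± 0.805 to 18.8 ± 2.01 CPM. Mpo, the gene of a neutrophil granule peroxidase on chromosome 11, fell from 189 ± 37.5 to 11.3 ± 3.25 CPM. Gzmb, which encodes a granule protease, fell from 191 ± 12.4 to 35.5 ± 5.01 CPM. Cd48, whose protein was gated against at the sort, fell from 339 ± 41 to 133 ± 5.66 CPM.

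In total, 73 genes rose and 43 fell in the young libraries labelled Pbx1 among 15335 tested. The number of calls went from 116 to 70, 76 and 75 without young_Pbx1 replicates 1, 2 and 3. It was 377 with DESeq2 and 176 without a filter on low counts. Among the genes with the largest rise were Dlk1 (log2 fold change 4.07 ± 0.52), Thbd (2.97 ± 0.30), Paqr5 (2.81 ± 0.23), Slc35d3 (2.51 ± 0.21) and Nupr1 (2.19 ± 0.25). Thbd encodes thrombomodulin, and Nupr1 a stress-induced nuclear protein. Further rises were seen in Tnip3 (1.87 ± 0.22), Pcp4l1 (1.86 ± 0.23), Efcc1 (1.78 ± 0.23) and Lincred1 (1.66 ± 0.23). Mpo changed by -4.06 ± 0.43 and Gzmb by -2.43 ± 0.23, with adjusted p values of 2.65e-04 and 1.49e-04. Perp, a p53 target of cell junctions, changed by -1.92 ± 0.24, and Hk3, a hexokinase of myeloid cells, by -1.72 ± 0.12. Alox5, the 5-lipoxygenase gene, changed by -1.58 ± 0.16 and Rufy4 by -1.75 ± 0.29. Ctsg, the cathepsin G gene, fell by 2.34 ± 0.39, with the call lost without young_Pbx1 replicate 2 or 3 (adjusted p up to 0.0681). Gata1, a factor of red cells and platelets, fell by 2.32 ± 0.46, and 6 of 12 fits without 1 library lost its call, with an adjusted p up to 0.13.

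The stem cell list had 2 risen and 1 fallen member among 29 tested in young cells, and 6 risen and 1 fallen adjusted over the list alone. Hlf (1.42 ± 0.11) and Procr (1.06 ± 0.13) rose, and Slamf1, the gene of CD150, fell by 1.21 ± 0.19. On the list of genes known to be high in aged HSCs, 3 rose and 2 fell among 32. Mmrn1, a platelet protein gene, rose by 1.12 ± 0.09, and Vwf, the von Willebrand factor gene, fell by 0.83 ± 0.12. On the megakaryocyte list 3 rose and 2 fell among 23, with Trpc6 up by 1.29 ± 0.13. Pf4, the platelet factor 4 gene, was up by 1.03 ± 0.19. Its call was lost without each young_Pbx1 library, with an adjusted p up to 0.0675. Of the cytokine receptors, Flt3 rose by 1.62 ± 0.18 and Csf2rb fell by 0.58 ± 0.07, with 29 others not called. On the endothelial list 2 rose and 1 fell among 13, and 9 members were lower, with a median of -0.64. Adgrl4 rose by 1.43 ± 0.13, and Pecam1 fell by 0.53 ± 0.09, with the call lost in 3 of 12 fits without 1 library (adjusted p up to 0.0703). On the neutrophil list 1 gene rose, 2 fell and 10 were not called. Among these, Prtn3, a protease gene of the same granules as Mpo, stood at 114 and 110 CPM in mock and Pbx1-labelled libraries. Lyz2, the lysozyme gene, stood at 120 and 121 CPM. Prtn3 and Lyz2 were chosen after their values were seen. On the list of homeobox partners Pknox1, which encodes a binding partner of PBX proteins, fell by 0.89 ± 0.14. Pbx2, Pbx3, Pbx4, Meis1 and Hoxa9 were not called, with log2 fold changes of 0.11, 0.93, 0.24, -0.16 and 0.43.

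Of 32 lists, camera called 11 in young cells with the preset correlation, and 1 held with an estimated correlation. It was the mast cell and basophil list, with a median log2 fold change of -1.27 and 12 of 14 members lower. Its adjusted p was 8.39e-07, or 0.0113 with an estimated correlation. Immediate early genes were higher in 19 of 20 members (median 0.54, adjusted p = 2.65e-04, or 0.446 with an estimated correlation). Of the immediate early genes 0 were called singly by edgeR, also when adjusted over the list alone.

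The second question was what the Pbx1 vector changed in old HSCs. Hlf, Procr and Mmrn1 were higher, and Mpo, Gzmb and Cd48 lower, in the libraries labelled Pbx1. Hlf rose from 74.9 ± 3.30 to 180 ± 19.1 CPM (SD, n = 3 each), Procr from 30.8 ± 1.41 to 61.6 ± 4.58 CPM and Mmrn1 from 352 ± 18.7 to 695 ± 70 CPM. Mpo fell from 55.0 ± 23.3 to 3.32 ± 2.03 CPM, Gzmb from 38.6 ± 13.4 to 6.22 ± 1.45 CPM and Cd48 from 51.2 ± 7.39 to 14.5 ± 2.68 CPM.

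In the old libraries 44 genes rose and 74 fell. This count of 118 depended on single libraries, and also on the test, the filter and the groups fitted, as given in the section on processing. It was 35 and 38 without old_mock replicates 1 and 3, and 61 without old_Pbx1 replicate 2. It was also 65, 67 and 76 without young_Pbx1 replicates 1, 2 and 3, and 228 without young_mock replicate 3, fits that share 1 estimate of spread across groups and also tested more genes. Old libraries of the same replicate number correlated at 0.17, 0.296 and 0.325 across 7942 genes after removal of the group means. Between ages, where no mouse is shared, libraries of the same number correlated at 0.0416, 0.113 and 0.302 in mock. With the Pbx1 label these values were 0.0629, 0.046 and 0.261. The labels do not say what the numbers share, so a pairing of the old libraries is possible but not established. With the replicate number as a block 101 genes rose and 115 fell, and 116 of the 118 calls were among them. With library sizes computed without Pbx1 the split was 43 risen and 115 fallen. Pbx1 held too small a share of the counts for its removal alone to do this. List medians moved down slightly under this scaling, as for S phase from -0.392 to -0.414 and for p53 targets from 0.557 to 0.536. The calls were thus sensitive to a small offset in scaling, whose cause was not tested.

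Among the largest rises in old cells were Flt3 (1.67 ± 0.18), Paqr5 (1.57 ± 0.22), Pcp4l1 (1.55 ± 0.22), Slc35d3 (1.49 ± 0.20) and Hlf (1.27 ± 0.10). Nupr1 rose by 1.56 ± 0.24, with the call lost without old_mock replicate 1 or 3 (adjusted p up to 0.0605). Mpo changed by -4.07 ± 0.45 and Gzmb by -2.64 ± 0.24, with adjusted p values of 5.87e-04 and 1.80e-04. Cd244 and Cd48, which encode a receptor and its ligand, changed by -1.99 ± 0.20 and -1.81 ± 0.15. The growth factor gene Fgf3 changed by -1.26 ± 0.15, the prostacyclin receptor gene Ptgir by -1.25 ± 0.19 and the melanocortin receptor gene Mc5r by -1.23 ± 0.13. Hk3 changed by -1.17 ± 0.12, Lrrc20 by -1.19 ± 0.18 and Alox5 by -1.12 ± 0.16. Pbx2, Pbx3, Pbx4, Meis1 and Hoxa9 were not called in old cells, with log2 fold changes of 0.25, 0.10, 0.56, -0.18 and 0.25.

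On the stem cell list 3 genes rose and 0 fell among 29 in old cells, and 7 rose and 2 fell adjusted over the list alone. Procr rose by 1.00 ± 0.12. Mllt3, a regulator of HSC maintenance, rose by 0.79 ± 0.12 and lost its call without old_mock replicate 1 or 3 (adjusted p up to 0.0548). On the aged HSC list 2 genes rose and 0 fell among 32, and 9 rose and 3 fell adjusted over the list alone. Mmrn1 rose by 0.98 ± 0.08, while Vwf was not called (-0.46, adjusted p = 0.0865). On the mast cell and basophil list 4 genes fell among 14. Cpa3, a mast cell carboxypeptidase gene, fell by 2.20 ± 0.35. Mcpt8 had 188 counts in the old_mock libraries and 0 in the old_Pbx1 libraries, at least 56.6-fold lower against a floor of 3 counts over the group. Its call was lost in 9 of 12 fits without 1 library, with an adjusted p up to 0.0983. The adjusted p of this list was 1.07e-04, or 0.0643 with an estimated correlation. Pknox1 fell by 1.10 ± 0.14, as in young cells.

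Members of the replication and sterol lists were lower in old libraries labelled Pbx1, mostly by small shifts, and neither list was called with an estimated correlation. All 44 tested S phase genes were lower, by a median of -0.39. Of them, 4 fell over all genes and 30 fell adjusted over the list alone (camera adjusted p = 5.46e-19, or 0.30 with an estimated correlation). Mcm4, a subunit of the replicative helicase, fell by 0.52 ± 0.09. Without old_mock replicate 1 or 3 it was not called (adjusted p up to 0.0815). Mcm5 (-0.52), Mcm6 (-0.37) and Dtl (-0.37) lost their calls in 9, 8 and 10 of 12 fits without 1 library, with adjusted p values up to 0.183, 0.17 and 0.206. Cholesterol synthesis genes were lower in 23 of 24 members, by a median of -0.46. The median was -0.29 without old_Pbx1 replicate 2, the library that lay apart on a principal component. Of the 24 members, 5 fell over all genes and 19 adjusted over the list alone (adjusted p = 1.22e-13, or 0.326 with an estimated correlation). Mvd, a mevalonate pathway enzyme gene, fell by 0.89 ± 0.12. Nsdhl fell by 0.55 ± 0.10 and lost its call without each old_mock library (adjusted p up to 0.103). Ribosome biogenesis genes were lower in 33 of 35 members by a median of -0.30, and 1 of them, Dkc1, fell (adjusted p = 1.59e-11, or 0.326 with an estimated correlation). The call of Dkc1 was lost in 4 of 12 fits without 1 library, with an adjusted p up to 0.109.

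In the same libraries p53 targets were higher in 23 of 26 members, by a median of 0.56. By edgeR 0 rose over all genes, 13 rose adjusted over the list alone, and Perp fell (camera adjusted p of the list 1.43e-05, or 0.30 with an estimated correlation). The call of Perp was lost in 10 of 12 fits without 1 library, with an adjusted p up to 0.138. Genes of antigen presentation had 3 risen members among 22 and 9 adjusted over the list alone (adjusted p = 1.94e-05, or 0.326 with an estimated correlation). H2-D1 (0.32), H2-K1 (0.36) and H2-T22 (0.59), which can share reads, lost their calls in 8, 10 and 7 of 12 fits without 1 library. Their adjusted p values then reached 0.143, 0.207 and 0.184. Camera called 13 of 32 lists in old cells with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0643. Fry called 9.

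Genes changed under the Pbx1 label overlapped between the ages. Of the genes called at either age, 44 were called at both, 22 higher and 22 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.209 and 0.207 genes (one-sided Fisher's exact test, p = 4.72e-41 and 3.36e-41). The comparisons share no library, but 1 fit gave each gene a spread common to both, and genes are not independent units. The p values are therefore descriptive. The shared genes included Hlf, Procr, Mmrn1, Flt3, Paqr5 and Slc35d3 among those risen. They included Mpo, Gzmb, Cd48, Hk3, Alox5 and Pknox1 among those fallen. The number shared went from 44 to 22, 29 and 24 without old_mock replicates 1, 2 and 3, and to 28, 25 and 27 without young_Pbx1 replicates 1, 2 and 3. With the replicate number as a block, 68 were shared. Across the 190 genes called at either age, 180 changed in the same direction at both, with r = 0.607 between the log2 fold changes. Over all 15335 genes r was 0.109, and genes are not independent replicates in either value.

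**Figure D2:**
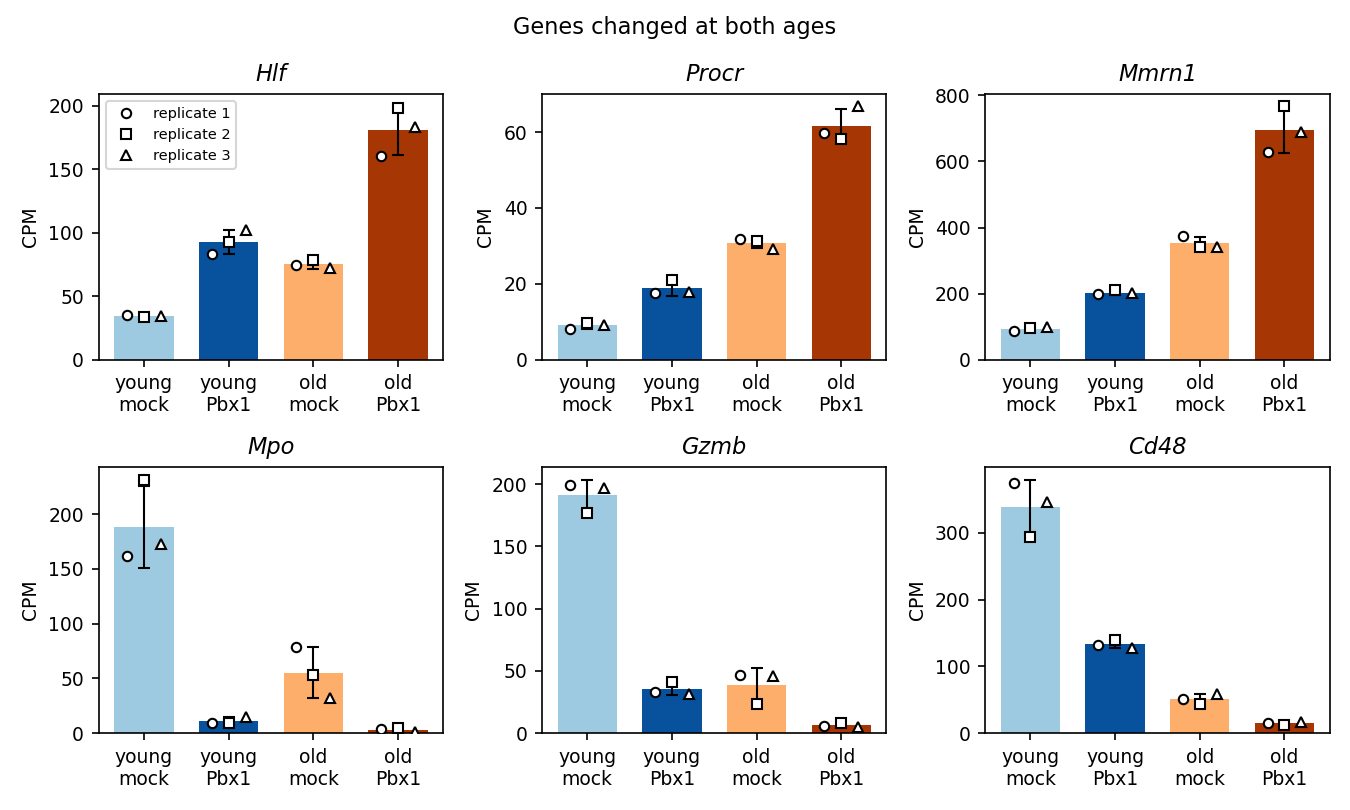
Levels of 6 genes changed at both ages, in CPM on the y axes, for the 4 groups on the x axes, with bars for means, error bars for SDs of 3 libraries and symbols for single libraries. Hlf, Procr and Mmrn1 were higher and Mpo, Gzmb and Cd48 lower in the libraries labelled Pbx1 at both ages, and from young_mock to old_Pbx1 Mmrn1 went from 93.6 to 695 CPM and Cd48 from 339 to 14.5 CPM.

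**Figure D3:**
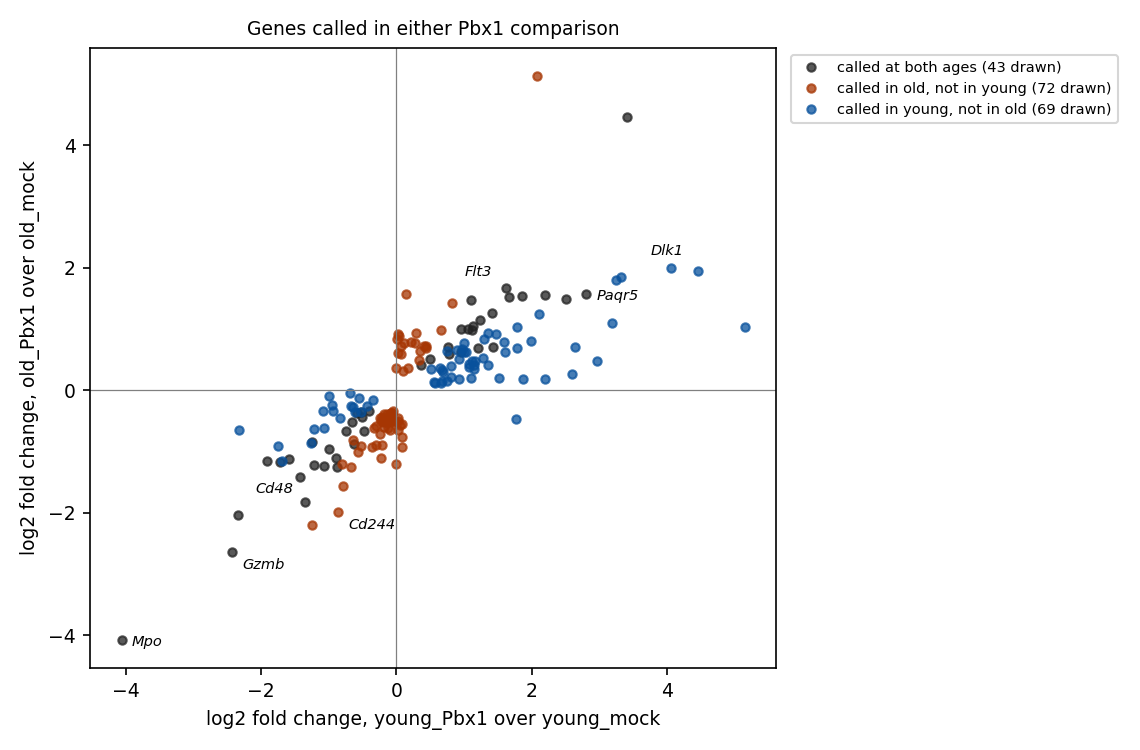
Log2 fold changes of genes called in either Pbx1 comparison, young cells on the x axis and old cells on the y axis, with 1 point per gene. Colours separate 43 genes called at both ages, which lie in the quadrants of equal sign, 69 called in young and not old cells and 72 called in old and not young cells, and another 6 genes with 0 counts in every library of a group are not drawn.

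Whether the effect of the Pbx1 label differed by age was tested as an interaction. By edgeR 0 genes differed, with 1000 at an unadjusted p under 0.05 and a smallest adjusted p of 0.207. DESeq2 called 30 genes, limma-voom 0 and edgeR without a filter on low counts 5, and edgeR called 1 without young_mock replicate 2. Camera called 7 lists with the preset correlation and 0 with an estimated correlation. The log2 difference, old minus young, had a median of -0.55 for cholesterol synthesis genes, with 0 of 24 members positive (adjusted p = 6.36e-15, or 0.662 with an estimated correlation). Without old_Pbx1 replicate 2 this median was -0.35. For S phase genes the median was -0.33, with 1 of 44 members positive (adjusted p = 5.43e-13, or 0.736 with an estimated correlation). For p53 targets it was 0.47, with 20 of 26 members positive (adjusted p = 6.49e-05, or 0.662 with an estimated correlation).

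The third question was how old HSCs differed from young HSCs after mock infection. Old mock libraries held more transcripts of Aldh1a1, Vwf and Selp and fewer of Cd48 and Gzmb. Aldh1a1, a retinal dehydrogenase gene on chromosome 19, rose from 14.3 ± 0.956 to 179 ± 22.5 CPM (SD, n = 3 each). Vwf rose from 51.9 ± 9.70 to 310 ± 23.4 CPM and Selp, the P-selectin gene, from 139 ± 14.9 to 466 ± 30.3 CPM. Cd48 fell from 339 ± 41 to 51.2 ± 7.39 CPM and Gzmb from 191 ± 12.4 to 38.6 ± 13.4 CPM. In this and every contrast of old with young libraries, age went together with the number of mice pooled, the CD41 gate and sex-linked transcripts. Xist had between 0 and 25 counts in each young library and between 1717 and 2850 in each old library. Ddx3y, on the Y chromosome, had between 2228 and 3457 counts in young and between 0 and 21 in old libraries. By these transcripts the young libraries were male and the old ones female. An effect of age therefore cannot be told apart from an effect of sex, also for genes on other chromosomes.

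By edgeR 1676 genes rose and 1644 fell with age in mock libraries. The count of 3320 went to 2019, 2113 and 2141 without old_mock replicate 2, old_mock replicate 1 and young_mock replicate 3. Without genes on X and Y it was 3238, which removes no effect of sex on other chromosomes. Large rises were measured for Gda (5.28 ± 0.53), Clec1a (4.74 ± 0.38), P2rx7 (4.72 ± 0.32), Clu (3.68 ± 0.20) and Aldh1a1 (3.65 ± 0.13). On the aged HSC list 27 genes rose and 0 fell among 32, with a median of 2.34 (adjusted p = 8.64e-20, or 0.026 with an estimated correlation). Mmrn1 rose by 1.91 ± 0.09 and Vwf by 2.58 ± 0.12. On the stem cell list 21 genes rose and 0 fell among 29 (adjusted p = 3.39e-15, or 0.026 with an estimated correlation). Procr rose by 1.77 ± 0.13, Esam by 1.51 ± 0.11 and Mecom by 1.43 ± 0.11. Megakaryocyte genes had 12 risen among 23, with Mpl, the thrombopoietin receptor gene, up by 0.65 ± 0.06 (adjusted p of the list 1.12e-07, or 0.0452 with an estimated correlation). Pbx1 itself rose by 0.79 ± 0.16, Pbx3 by 1.72 ± 0.23, Hoxb5 by 2.72 ± 0.40, Hoxa10 by 1.38 ± 0.22 and Meis1 by 0.43 ± 0.07. The list of homeobox partners had an adjusted p of 0.00155, or 0.0813 with an estimated correlation.

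Interferon response genes rose in 24 of 40 members with age in mock libraries, and 28 rose adjusted over the list alone (adjusted p = 4.21e-12, or 0.0441 with an estimated correlation). Oasl2 rose by 1.89 ± 0.21, Igtp by 1.06 ± 0.12 and Sp100 by 0.95 ± 0.11. Antigen presentation genes rose in 16 of 22 members (adjusted p = 2.23e-10, or 0.104 with an estimated correlation). H2-Q7 rose by 1.3 ± 0.14 and H2-D1 by 0.75 ± 0.06, with reads that can be shared among H2 genes. Of the p53 targets 15 rose and 1 fell among 26, with Zmat3 up by 2.88 ± 0.32 and Phlda3 by 1.57 ± 0.22 (adjusted p = 2.19e-04, or 0.104 with an estimated correlation). Of the S phase genes 35 fell and 0 rose among 44, with Mcm5 down by 0.77 ± 0.10 and Mcm4 by 0.60 ± 0.09 (adjusted p = 4.56e-17, or 0.104 with an estimated correlation). Of ribosome biogenesis genes 32 fell and 0 rose among 35, with Nop56 down by 0.50 ± 0.07 and Npm1 by 0.42 ± 0.07 (adjusted p = 1.32e-15, or 0.104 with an estimated correlation). Oxidative phosphorylation genes fell in 24 of 42 members, with Cyc1 down by 0.59 ± 0.10 and Atp5b by 0.36 ± 0.06 (adjusted p = 1.84e-11, or 0.104 with an estimated correlation). Cpa3 fell by 2.08 ± 0.33, Dpp4 by 2.45 ± 0.31, Scin by 2.18 ± 0.22 and Flt3 by 1.53 ± 0.18. Prtn3 rose by 0.75 ± 0.08.

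The fourth question was how old and young HSCs differed in libraries labelled Pbx1. Old libraries again held more transcripts of Aldh1a1, Vwf and Mmrn1 and fewer of Cd48, and also fewer of Mcm4. Aldh1a1 rose from 10.1 ± 1.12 to 189 ± 14 CPM (SD, n = 3 each), Vwf from 29.3 ± 1.52 to 226 ± 4.70 CPM and Mmrn1 from 203 ± 6.13 to 695 ± 70 CPM. Cd48 fell from 133 ± 5.66 to 14.5 ± 2.68 CPM and Mcm4 from 442 ± 8.46 to 206 ± 12.9 CPM. By edgeR 2285 genes rose and 2335 fell, and 2696 genes differed by age in both arms in the same direction, against 500 for independent lists. The number in opposite directions was 4. The arms share no library, but they share the fit and its spread for each gene.

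Genes with large rises between the libraries labelled Pbx1 were Rorb (7.16 ± 0.92), Clca3a1 (5.97 ± 0.51), Wwtr1 (5.15 ± 0.51) and Thbs1 (5.09 ± 0.69). The value of Rorb ranged from 6.576 to 13.16 in fits without 1 library, so the size of its rise is uncertain. Ly6a, the Sca-1 gene, rose by 3.07 ± 0.22 and Mllt3 by 1.73 ± 0.13. Pbx1 rose by 1.32 ± 0.17 and Meis1 by 0.40 ± 0.07. Pbx3 rose by 0.89 ± 0.23, a call lost without young_Pbx1 replicate 2 (adjusted p = 0.0524). Hspa1a and Hspa1b were called as well, on 1 library. They stood at 1003 and 1352 CPM in old_Pbx1 replicate 2 and at no more than 1.46 and 3.08 CPM in any other, and the adjusted p rose to 0.0949 and 0.0564 without it. Cd244 fell by 2.60 ± 0.20, Igfbp7 by 3.30 ± 0.60 and Nlrc3 by 3.13 ± 0.55.

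Of the S phase genes 42 of 44 fell in old libraries labelled Pbx1 against young ones, by a median of -0.94. The adjusted p was 1.05e-22, or 0.0926 with an estimated correlation. Of the cholesterol synthesis genes 21 of 24 fell, with Lss down by 1.39 ± 0.16 and Dhcr24 by 1.40 ± 0.17 (adjusted p = 7.81e-11, or 0.178 with an estimated correlation). In mock libraries 3 of 24 had fallen. Of the p53 targets 19 of 26 rose, with Phlda3 up by 2.18 ± 0.23, Ccng1 by 1.38 ± 0.13 and Bax by 0.73 ± 0.09 (adjusted p = 9.90e-08, or 0.0736 with an estimated correlation). On the aged HSC list 27 of 32 genes rose (adjusted p = 2.04e-19, or 0.034 with an estimated correlation). It was the 1 list of 17 called that held with an estimated correlation.

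The last question was whether the effect of the Pbx1 label in old HSCs ran against the effect of age. Genes called in both contrasts mostly ran with it. Of 44 genes that rose in old libraries labelled Pbx1, 31 were also higher in old than in young mock libraries, against 4.81 for independent lists. Of 74 that fell, 48 were also lower with age, against 7.93. The remaining genes called in both were 4 that rose with the label and were lower with age, such as Flt3, and 5 with the opposite signs. Mmrn1, Procr and Nupr1 rose in both contrasts, and Mpo, Gzmb, Cd48 and Cpa3 fell in both. The old_mock libraries enter these contrasts with opposite signs, so with no effect the fold changes are negatively related. Across all genes the covariance was -0.19, against a mean of -0.34 (SD 0.0119) in 20 simulations with unchanged groups, a difference of 0.145. The simulations did not model a possible pairing of the old libraries by replicate number, which alone would make the covariance less negative. The difference depended on which genes were tested. Without a filter the covariance was -1.175 against a simulated -1.045. Without 1 library at a time it lay between -0.773 and -0.376, and differed from simulations of the same fits by -0.0489 (without old_mock replicate 3) to 0.0705, with 11 of 12 differences positive. Over the genes of the full set alone these differences lay between 0.0526 (without old_mock replicate 3) and 0.18. The correlation was -0.15, against a simulated mean of -0.50. On the scale of log2 CPM the covariance was -0.015 with the shared libraries, and had a mean of 0.15 over 3 choices with no old_mock library in both contrasts. The old_mock library of the age contrast still shared its number with an old_Pbx1 library, and a pairing by number can raise this mean. No value for unchanged groups was simulated for it. The young Pbx1 effect and age share the young_mock libraries with equal sign, and their covariance was 0.67 against a simulated 0.33, while their correlation was 0.45 against a simulated 0.49, so no excess showed on that measure. Of 73 genes risen in young libraries labelled Pbx1, 52 were higher with age, against 7.98 for independent lists, and 18 of 43 fallen genes were lower, against 4.61. With shared young_mock libraries these counts are positively related by construction.

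**Figure D4:**
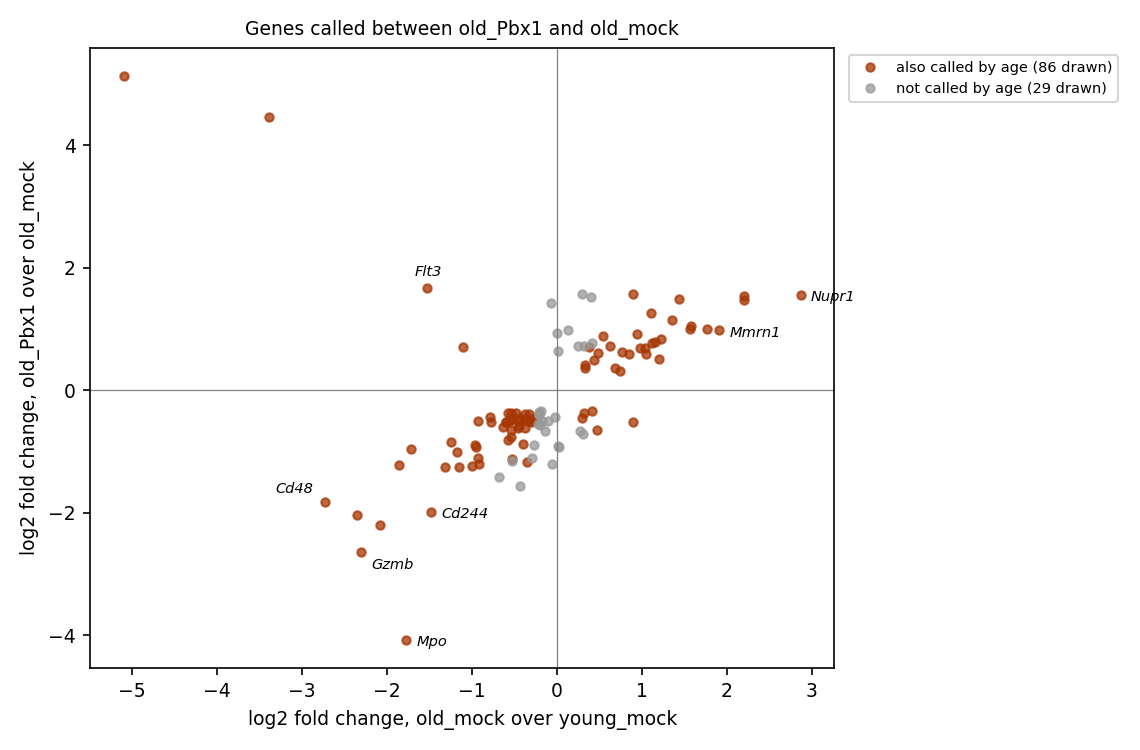
Log2 fold changes of genes called between old_Pbx1 and old_mock libraries, on the y axis, against those between old_mock and young_mock libraries, on the x axis, with 1 point per gene. Colours separate 86 genes also called by age, most in the quadrants of equal sign with Flt3 among the exceptions, from 29 that were not, and another 3 genes with 0 counts in every library of a group are not drawn.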

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

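The tests of exchanged names, of vector reads, of admixed progenitors, of old_Pbx1 replicate 2 and of correlation among list members were chosen after the results were seen, while the 100 exchanges of names were planned.

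For 7 of 32 gene lists the log2 difference between Pbx1-labelled and mock libraries differed between old and young cells, by camera on the interaction with the preset correlation. With an estimated correlation 0 of the 7 were called, and the smallest adjusted p was 0.662. Medians of the difference, old minus young, were -0.548 for cholesterol synthesis (adjusted p = 6.36e-15, 0 of 24 members positive) and -0.332 for S phase (5.43e-13, 1 of 44 positive). They were -0.179 for ribosome biogenesis (5.02e-05, 6 of 35 positive) and -0.299 for the integrated stress response (1.33e-04, 4 of 24 positive). They were 0.469 for p53 targets (6.49e-05, 20 of 26 positive), 0.132 for ribosomal proteins (1.09e-04, 45 of 45 positive) and 0.375 for the aged HSC signature (0.0494, 22 of 32 positive). Without old_Pbx1 replicate 2 the cholesterol synthesis median was -0.352, and without young_mock replicate 3 the ribosome biogenesis median was -0.306. The call of ribosomal proteins was lost without young_mock replicate 1 (adjusted p = 0.157). These lists drew attention because the interaction itself passed its threshold, while edgeR called 0 single genes in it, with 1000 at an unadjusted p under 0.05 and 30 by DESeq2.

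The first pattern was that Pbx1 was not higher in the libraries labelled Pbx1. In the old libraries the 95% interval of the log2 fold change lay between -0.514 and 0.234. It excludes an exchange of the mock and Pbx1 names with a vector that raises counted Pbx1 at least 2-fold. It equally excludes such a vector with the names as given, so it does not decide which naming is right. In the young libraries the interval lay between -1.05 and -0.289. It does not exclude an exchange with such a vector, but excludes such a vector with the names as given. An exchange in the young libraries alone would turn the 44 genes called at both ages in the same direction into 44 opposite ones. An exchange at that age alone stays open only with a response that reverses with age. Where reads of the vector's Pbx1 were not counted, Pbx1 levels decide nothing. An exchange at both ages then stays open, as it keeps the directions of the 44 genes equal. That the name marks no difference between the libraries was excluded: of 100 exchanges of names within each age, 1, the real one, gave 44 genes called at both ages in the same direction. It stays open whether reads of the vector's Pbx1 were not counted at the mouse gene, since the count table held 0 entries for a vector, and a biological fall of endogenous Pbx1 was not tested.

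The second pattern was the fall of the granule genes Mpo and Gzmb in the libraries labelled Pbx1 at both ages, without a call of the neutrophil list. Elane, abundant in neutrophil progenitors beside Mpo, stood at 0.720 CPM in young_mock libraries against 189 for Mpo. This argues against fewer admixed progenitors of the kind rich in Elane, in young cells alone. Progenitors with Mpo and little Elane were not tested, nor were old libraries, so fewer admixed neutrophil progenitors stay open as a cause. Prtn3 (114 and 110 CPM in young mock and Pbx1-labelled libraries) and Lyz2 (120 and 121 CPM), chosen after their values were seen, did not follow Mpo, while Ctsg fell in young cells. Fewer admixed mast cell and basophil progenitors may be the cause and cannot be told apart from a change within HSCs, since 12 of the 14 tested members of that list were lower in young libraries labelled Pbx1, against 9 of 14 in old ones. The sort by CD150, CD48 and lineage markers preceded the culture and would not remove cells that arose in it, and a biological change within HSCs was not tested.

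The third pattern was the set of 7 lists whose difference between Pbx1-labelled and mock libraries depended on age. For the lists other than the aged HSC signature, the calls with the preset correlation did not rest on old_Pbx1 replicate 2 alone. All 6 were called in the same direction without it, though the cholesterol synthesis median moved from -0.548 to -0.352. For the aged HSC signature the adjusted p was 0.282 without that library, but the call was also lost without young_mock replicate 2 (0.344) or 3 (0.0755), young_Pbx1 replicate 2 (0.193), and old_mock replicate 1 (0.101) or 3 (0.128), so no single library was shown to be the cause. Correlation among the members of a list above the preset value may account for the calls, since 0 of the 7 lists were called with an estimated correlation. Chance was not excluded either, as 40 of 100 exchanges of names gave at least 7 lists. Names were exchanged separately within each age, so some exchanges carry part of the common Pbx1 effect into the interaction. The 40 therefore do not measure chance alone. An effect of age on the response stays open, as do pooling, the CD41 gate and sex, none of which the design separates from age.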

How the results depend on the processing

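The replicate number as a block within each age, the covariance with no shared old_mock library, the simulations of fits without 1 library and the age counts without X and Y were chosen after seeing the data. Unless a construction is named, the cause was not tested.

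DESeq2 called more genes than edgeR: 377 in place of 116 for Pbx1 in young cells, 809 in place of 118 in old cells, 128 in place of 44 shared between ages, and 30 in place of 0 for the interaction. By its test the fall of Pbx1 in young cells, -0.6754, passed the threshold. Without a filter on low counts the Pbx1 counts were 176 in young and 310 in old cells, and the interaction count was 5. With a strict filter, which tests fewer genes, the old count was 249. With only the groups compared, which leaves fewer residual degrees of freedom, it was 43. With library sizes without Pbx1 it was 158, with 43 higher and 115 lower (27.2% higher, against 37.3% with 44 and 74). This move went with a small offset in scaling, as Pbx1 itself held a very small share of the counts. The replicate number as a block gave 216 genes in old cells and 68 shared genes, and as a block within each age 191 in old cells.

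Camera with an estimated correlation called 1 list in place of 11 for Pbx1 in young cells, 0 in place of 13 in old cells, 6 in place of 21 for age in mock, 1 in place of 17 for age in Pbx1-labelled libraries and 0 in place of 7 for the interaction. Fry called 1 in young cells, 9 in old cells, 19 for age in mock, 22 for age in Pbx1-labelled libraries and 0 for the interaction.

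The covariance of the age effect with the Pbx1 effect in old cells, -0.1945, changed sign with a prior count of 5 (0.008931) and among genes called in either comparison (0.165). With no shared old_mock library it was 0.1497, on the scale of log2 CPM, where it was -0.015 with the shared libraries, so about as much of the move goes with the scale as with the sharing. A pairing of the old libraries by replicate number, which is possible but not established, would still link the contrasts there and can raise the value. The covariance was -1.175 without a filter, against -1.045 in simulations of unchanged groups, and -0.2165 with the replicate number as a block, against -0.3227. These simulations did not model such a pairing. Without 1 library the covariance lay between -0.7733 and -0.376. These fits let between 15884 and 16008 genes through the filter, against 15335, and unchanged groups simulated for them gave -0.743 to -0.442. The difference from the simulated value lay between -0.0489 and 0.0705 over all their genes and between 0.0526 and 0.18 over the genes of the full set. Of the former, 11 of 12 were positive and 1, without old_mock replicate 3, was negative, so the excess over unchanged groups was smaller when these genes were added.

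Without 1 library at a time, the Pbx1 counts ranged from 70 (without young_Pbx1 replicate 1) to 119 in young cells and from 35 (without old_mock replicate 1) to 228 (without young_mock replicate 3) in old cells. Shared genes ranged from 22 to 46, age in mock from 2019 to 3658 and in Pbx1-labelled libraries from 3442 to 4877, and the interaction from 0 to 1. The change of Pbx1 ranged from -0.7975, which passed the threshold, to -0.5197 in young cells. In old cells it ranged from -0.2441 to -0.00488 and passed in none of the 12 fits. List counts ranged from 10 to 15 and 11 to 16 for Pbx1 in young and old cells, and from 6 to 9 for the interaction.

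The age counts stayed within 1.5 times their value under each alternative other than leaving out a library, and without X and Y they were 3238 and 4467. Of 4224 values of single named genes under the alternatives, 3963 kept their direction and side of the threshold, 242 no longer passed it, 19 newly passed it and 0 reversed a called direction. These totals pool stable age genes with less stable Pbx1 genes. In the age contrasts only Hspa1a, Hspa1b and Pbx3 lost calls, under 2, 2 and 1 alternatives. All other losses were in the Pbx1 comparisons, with up to 14 for 1 gene in old cells (H2-K1) and 11 in young cells (Emcn). Depth limits a fold against a group with 0 counts to a bound, as for Mcpt8 in old cells (at least 56.6-fold lower). In simulated data of the same depths genes changed 1.5-fold were recovered at 28% in young and 36% in old cells. Genes of low mean level were not among those changed.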

Other observations

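The test of neighbouring genes and the genes named in it were chosen after the data were seen. So were the heat shock genes other than Hspa1a and Hspa1b, and Ddit3, which is not a heat shock gene. The splits of the samples were planned.

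In the library old_Pbx1 replicate 2, Hspa1a stood at 1003 CPM, Hspa1b at 1352 and Hspb1 at 93.3, against at most 1.46, 3.08 and 0.523 CPM in any other library. Dnajb1 stood at 262 against at most 122 CPM, and Ddit3 at 171.5 against at most 84.5. Hsph1 (92.1 against 212), Hspa8 (2830 against 3918), Hsp90aa1 (741 against 1034) and Hsp90ab1 (2669 against 3599) were below the highest of the other libraries.

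Some genes that changed together in the libraries labelled Pbx1 lay close to each other on GRCm38. In young cells 9 pairs called in the same direction started within 250000 bases of each other, against a mean of 1.95 in random gene sets of the same sizes, of which a share of 6e-04 held as many. Among them, Lincred1 and Lmo2 started 57.0 kb apart, Thbd and Cd93 32.2 kb, Apobr and Nupr1 38.3 kb, Cd48 and Slamf1 85.9 kb, and Ctsg and Gzmb 159 kb. The young calls of Lmo2 and Ctsg were lost in 5 and 2 of 12 fits without 1 library (adjusted p up to 0.1 and 0.0681). In old cells there were 5 pairs against a mean of 1.94, a share of 0.0525, which leaves the question open there. Without predicted genes and families of like names there were 6 pairs in young cells (share 0.0155) and 4 in old cells (share 0.139). Shared regulation of neighbouring genes is a candidate explanation for the young pairs, with limits. Whether regulated genes cluster in general was not tested, reads carry no strand, and the 6 young pairs still hold Ctsg and Gzmb, which are related proteases, and Cd48 and Slamf1, which belong to 1 receptor family.

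Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05, as the smallest is 0.1. For Pbx1 in young cells the real split called 116 genes and the highest other 1, so 1 of 10 was as large. In old cells these were 118 and 0, with 1 of 10 as large, and 0 also among the splits that part as many replicate pairs. For age they were 3320 and 0 in mock and 4620 and 0 in Pbx1-labelled libraries, again 1 of 10 each. For lists, 4 of 10 splits called as many for Pbx1 in young cells (11, highest other 17) and 1 of 10 in old cells (13, highest other 11, or 7 among splits that part as many pairs). For age, 2 of 10 called as many lists in mock (21, highest other 21) and 2 of 10 in Pbx1-labelled libraries (17, highest other 18).

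For results that join both ages, 100 exchanges of names were drawn, the real one included. Chance was excluded for the 44 genes shared between ages, where the highest other was 0, and for the covariance of -0.1945, where the highest other was -0.2479, with 1 of 100 as large each. For the covariance this covers the full set of filtered genes alone, since without a filter it was -1.175 against a simulated -1.045, and without 1 library at a time it was -0.376 or lower. The exchanges also did not keep a possible pairing of the old libraries by replicate number, which would bear on the covariance. Chance was not excluded for the interaction, where the real names called 0 genes, so that all 100 are as large, and 40 gave at least 7 lists, with a highest other of 18. The highest other value for interaction genes, 363, came from the exchange that swaps all names at 1 age and keeps them at the other. Its interaction is the sum of the Pbx1 effects at both ages, so it carries their common part, and the next highest exchange called 8. Other exchanges closer to the real names at 1 age than at the other can carry some of this part too. The 40 exchanges with at least 7 lists therefore do not measure chance alone.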
